A study of Mus musculus with 30 samples.

How the data were processed

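The data are 3' RNA sequencing of mesenchymal cells of the mouse intestine (strain C57BL/6, per the labels). The animals carried a Cre transgene under the promoter of a collagen VI gene and the Rosa mTmG reporter. Cells of the colon were sorted as GFP-positive or GFP-negative (called Tomato in the labels) or left unsorted, in normal and in DSS-treated mice. Cells of the small intestine of normal mice were sorted as high GFP, low GFP or GFP-negative or left unsorted. Each of the 10 groups has 3 replicates per the labels, and replicate 1 of the unsorted small intestine was not analysed here. This leaves 29 libraries.

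Per the labels, RNA was purified on RNeasy columns, samples with an RNA integrity number over 7 were kept, libraries were made with the Lexogen QuantSeq 3' kit for Ion Torrent, and sequencing was done on an Ion Proton. This method primes at the poly(A) tail and reads near the 3' end, so 1 read stands for 1 transcript whatever its length, and no correction for gene length was made. Overlapping 3' ends on the same strand, and genes with near-identical copies, cannot be separated well by short reads. Overlapping genes on opposite strands can be separated if reads were counted by strand, which the sources used here do not say. Per the submitters' processing notes, reads were aligned with TopHat2 and Bowtie2 to mm10, and DESeq was used. Versions and settings of these tools, the counting program, the gene annotation, the filter that chose the genes of each table and the handling of reads that map to several places are not given in the sources used here.

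Values came as 14 tables that each hold a pair of groups, with 15019 to 18042 genes each. Per the file headers, the deposited scores are read counts that the authors normalised, and they are whole numbers, so the authors rounded them after scaling. Per the file headers, the authors also deposited a p-value and an FDR from their DESeq test, and log2 fold changes made from group means with 1 added. The deposited fraction of G and C bases per gene, given by the authors, was not used here. Coordinates are those of the authors' deposited tables, on mm10.

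Libraries of the normal colon, the DSS colon and the small intestine were each on their own scale. The tables that set DSS against normal cells held a further scale common to the 12 sorted colon libraries. This was checked by the ratio of each library's values on the common scale to those on its own scale, which was 0.836 to 0.844 in normal and 1.17 to 1.18 in DSS libraries, alike for GFP-positive and GFP-negative cells. The difference of the DSS responses was therefore tested on this scale. That the GFP-positive and GFP-negative tables share it was inferred from these ratios alone, as they have no library in common. Unsorted colon cells are not on it, so all 6 colon groups were not fitted together.

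Depth was estimated from the value of 1 read in each library, found as the spacing of its values (0.571 to 1.93 normalised counts per read). Estimated reads per library were 4085000 to 4416000 for GFP-positive, 3670000 to 3961000 for GFP-negative and 3178000 to 4277000 for unsorted cells of the normal colon. They were 2475000 to 3054000, 3013000 to 3373000 and 3207000 to 3843000 for those of the DSS colon. In the small intestine they were 1377000 to 2787000 for high GFP, 1792000 to 4028000 for low GFP, 1229000 to 3196000 for GFP-negative and 2836000 to 3527000 for unsorted cells. For GFP-positive libraries 1 and 3 and unsorted library 3 of the normal colon the spacing is so near 1 that it was not resolved. On 10 simulated libraries the largest error of this estimate was 0.233%. The simulated spacings were changed after a first run, because values typed for them also occurred among the results, and the estimates for the data did not change. In the data the error can be larger: GFP-positive library 1 of the normal colon was given 4225000 reads on its own scale and 3705000 on the common scale, and the ratio of its spacings differed by 14.2% from that of its values. A gene at 10 normalised counts rests on few reads, and its fold change is less precise than that of a gene at 1000. The 10 highest genes held 5.21% to 13.0% of the counts of a library, and 0 pairs of libraries were identical.

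Groups, comparisons, tests and gene lists were fixed before the data were examined. Because the values are normalised, the fallback fixed with the design was used: limma 3.58.1 in R 4.3.3 on log2(value + 1), with the mean-variance trend and robust variance, on genes with a mean of at least 10 in 1 of the groups. All adjusted p-values of genes are from limma, Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Only the 2 groups compared entered a fit, with no replicate block. The difference test used the 4 sorted colon groups. The labels give no mouse identity, so replicates were taken as separate samples.

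The 28 gene lists have 2 to 40 members: the pair of the Cre driver gene and the CD201 gene, telocyte, Cd34-positive fibroblast, smooth muscle, pericyte, endothelial, glia and neuron, interstitial cells of Cajal, mesothelial, immune, epithelial, erythroid, BMP ligand, BMP antagonist, Wnt ligand, R-spondin, Wnt inhibitor, growth factor (EGF, FGF, HGF, IGF), Hedgehog, collagen, matrix enzyme, basement membrane, cytokine and chemokine, interferon, cell cycle, vessel factor, dissociation and heat-shock, and mitochondrial. Lists overlap, and 11 of the 16 telocyte members are also in another list. Lists with at least 5 tested members were tested with camera (limma), with the correlation between genes preset at 0.01, and Benjamini-Hochberg over lists and comparisons. An adjusted p with an estimated correlation is given beside each call. Of 337 list tests, 174 passed with the preset and 0 with the estimate. With fry, a rotation test of limma, 157 passed. It gave the same direction for all 174, but both tests take the direction from the same genes and libraries, so this is no separate support. Counts of members refer to all genes of the comparison unless "adjusted over the list alone" is said.

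Overlaps between comparisons that share no library were tested with the Fisher exact test in each direction. In simulated data with 200 genes changed 4-fold in both colon contrasts, 184 were called in both. The spread there was a fixed value, not that of the libraries. Recovery of known changes was tested on simulated data with the same spread for all genes of a comparison, the median over its higher-read genes. With no change put in, 0 genes passed in every comparison. Genes were simulated as independent and with equal spread, so these figures may be too favourable.

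Genes named in the text follow a fixed rule. Col6a1, Procr, Pdgfra, Cd34, Foxl1 and Acta2 were chosen for every comparison. They are all given in the comparisons between sorted groups, and only some of them in those with unsorted cells and in the difference. In comparisons of sorted cells the 6 genes higher and 6 lower with the largest fold change are given (3 and 3 in those with unsorted cells and in the difference), among protein-coding genes past the threshold, with a mean of at least 20 CPM (normalised counts scaled to equal library sums) and replicates that do not overlap. For each list described, the 4 highest-read members past the threshold may be named, or a member not past. Other list members were named from the full lists after the values were seen. A few genes that this rule selects are not reported here.

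The authors' deposited table gives its own calls at an FDR of 0.05. In the authors' deposited table, 94 genes passed for the normal colon and 308 for the DSS colon (GFP-positive against GFP-negative), of which 81 and 304 passed here. In the authors' deposited table, 45 genes passed for DSS against normal GFP-positive cells and 76 for GFP-negative cells, of which 45 and 68 passed here. For the small intestine the authors' deposited table has 71, 47 and 20 genes (high GFP and low GFP against negative, and high against low), of which 29, 8 and 13 passed here.

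Alternatives tried were a pseudocount of 0.5, no filter on low values, a replicate block, a log2 fold change of at least 1, and leaving out each library. Chosen after the data were seen were rescaling by median ratios, equal totals, voom on estimated reads and, in the colon, fits with all groups of a scale. The fit with all 4 groups of the small intestine was planned. Data were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and data.table (version 1.17.8), and drawn with matplotlib 3.10.9.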

Results

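RNA was measured by 3' sequencing in mesenchymal cells isolated from the mouse intestine. The animals carried a Cre recombinase driven by the promoter of a collagen VI gene and the mTmG reporter, in which cells with Cre activity, and their descendants, turn from a red membrane protein (Tomato) to a green one (GFP). From the colon, GFP-positive, GFP-negative and unsorted cells were taken from normal mice and from mice given dextran sulfate sodium (DSS), a compound that injures the colon epithelium and causes colitis. From the small intestine of normal mice, cells with high GFP, low GFP and no GFP were taken, and unsorted cells beside them. The labels give 3 replicates for each of the 10 groups as separate samples, and p-values then measure the spread between these samples. In total 29 of the 30 labelled libraries were used, with 2 for the unsorted small intestine.

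Depth differed between tissues. Estimated reads per library, counted over the genes of each table, ran from 3670000 to 4416000 in the sorted groups of the normal colon, from 2475000 to 3373000 in those of the DSS colon and from 1229000 to 4028000 in those of the small intestine. Unsorted libraries had 3178000 to 4277000 estimated reads in the normal colon, 3207000 to 3843000 in the DSS colon and 2836000 to 3527000 in the small intestine. Gene levels below are normalised read counts as scaled by the authors. Fold changes are log2 values of the first-named group over the second, tested with limma at an adjusted p of 0.05. A fold change is the difference of group means of log2(value + 1), and for a gene with low counts or a library at 0 it can lie below or above the ratio of the mean levels. The tables of the normal colon, the DSS colon and the small intestine were normalised separately. The main tests were therefore made within a table, except the difference of DSS responses. That test joined the tables of DSS against normal cells, which were taken to share a scale. Some alternative fits also joined tables of the same scale. Levels set side by side across tables are not tested.

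**Figure D1:**
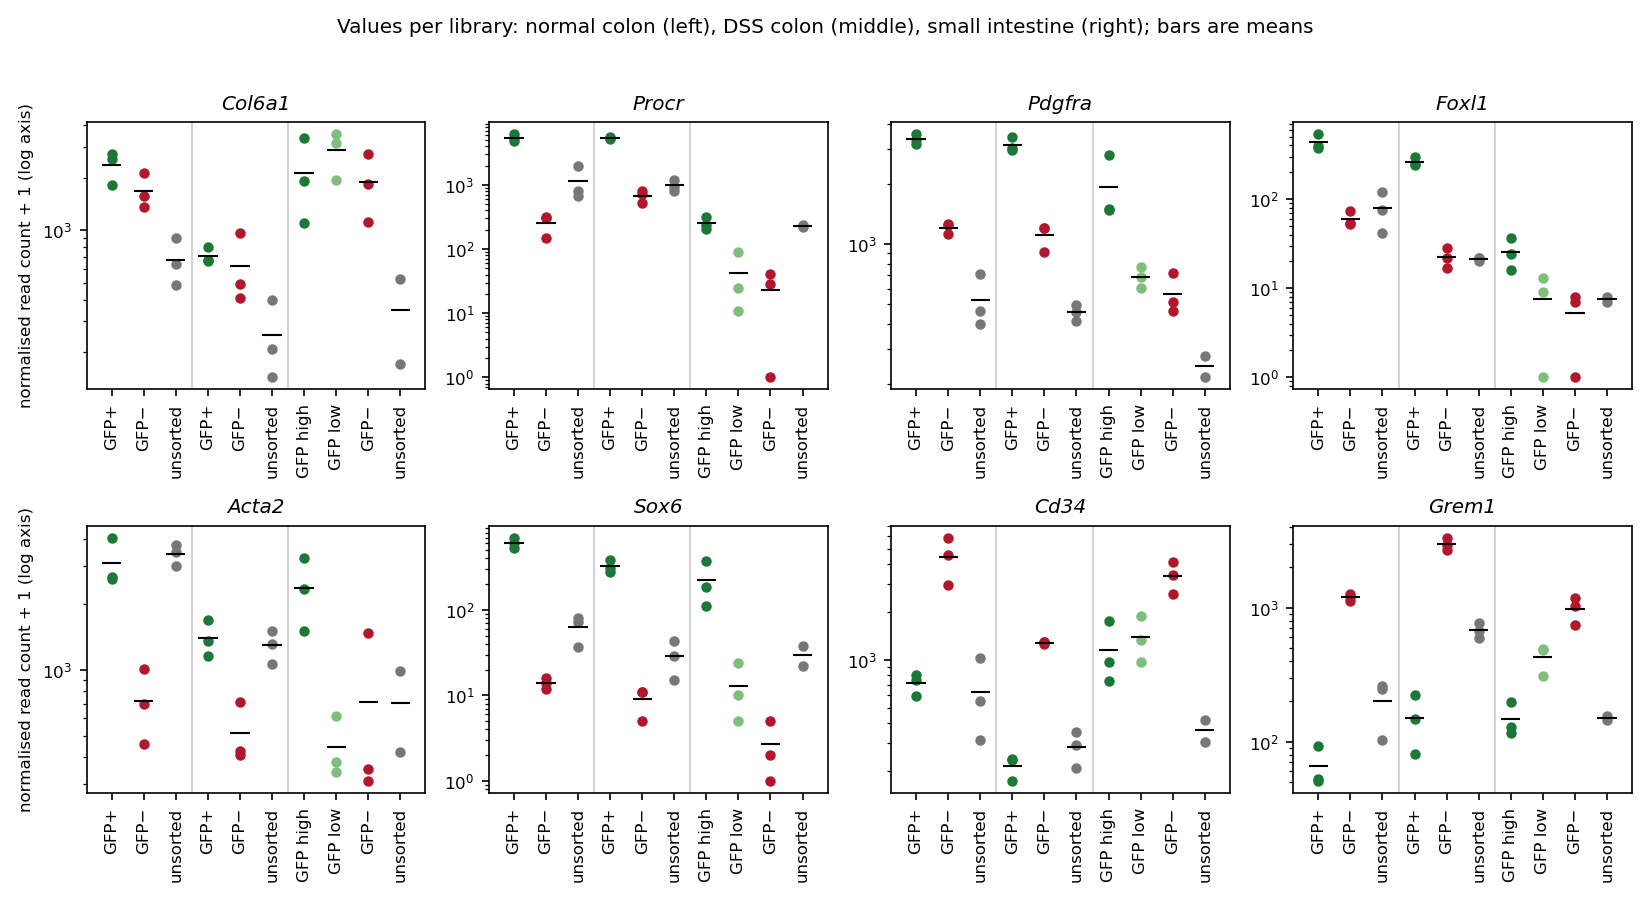
Normalised read counts of 8 genes in every library of the 10 groups, 1 point per library. The tables of the normal colon, DSS colon and small intestine were scaled separately by the authors.

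The first question was what the GFP-positive cells of the normal colon express that the GFP-negative mesenchymal cells beside them do not. Telocytes, the subepithelial fibroblasts with high Pdgfra, lie under the epithelium and secrete BMP and Wnt5a signals. Of their 16 tested genes 12 were higher in GFP-positive cells (adjusted p = 0.17 with an estimated correlation). Cd34-positive fibroblasts lie at the crypt base and in the submucosa. Of their 18 genes 13 were lower (adjusted p = 0.18 with an estimated correlation). Procr, which encodes the endothelial protein C receptor CD201, reached 5456 ± 667 against 256 ± 96.3 (SD, n = 3 each), a log2 fold change of 4.49 (adjusted p = 8.9e-05, chromosome 2, 155751117 to 155755471). Foxl1, a transcription factor of subepithelial telocytes, stood at 435 ± 87.3 against 59 ± 12.2 (SD, n = 3 each) (2.86, adjusted p = 0.00023, chromosome 8, 121127940 to 121130644). Cd34, a surface sialomucin, was lower at 714 ± 113 against 4463 ± 1471 (SD, n = 3 each) (-2.60, adjusted p = 0.00069, chromosome 1, 194938819 to 194961279).

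Of 13346 genes tested with limma, 798 passed an adjusted p of 0.05, 396 higher and 402 lower in GFP-positive cells. Pdgfra, the receptor for platelet-derived growth factor A, was higher (1.46, adjusted p = 0.0053, chromosome 5, 75152292 to 75198215) as was Acta2, smooth muscle actin (2.15, adjusted p = 0.0033, chromosome 19, 34241090 to 34255336). Col6a1, a chain of collagen VI, stood at 2369 ± 486 against 1687 ± 403 (SD, n = 3 each) and did not pass (0.49, adjusted p = 0.45, chromosome 10, 76708792 to 76726168). The 6 largest increases were in Wif1 (7.35), a secreted inhibitor of Wnt ligands, Spag5 (5.61), Sox6 (5.45), a transcription factor, Bean1 (5.02), the BMP family member Bmp3 (4.53) and Procr. Wif1 was read at 207 ± 42.5 against 0.333 ± 0.577 (SD, n = 3 each) (chromosome 10, 121033960 to 121100650) and Sox6 at 609 ± 88.05 against 13 ± 2 (SD, n = 3 each). The 6 largest decreases were in Edil3 (-4.41), Grem1 (-4.23), a secreted BMP antagonist, Dner (-4.12), the plasma cell gene Mzb1 (-3.68), Sfrp2 (-3.60), a secreted Wnt inhibitor, and Shisa3 (-3.59). Grem1 was read at 64.7 ± 23.7 against 1187 ± 70.6 (SD, n = 3 each) (chromosome 2, 113746164 to 113758646).

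Both fibroblast lists were then tested as groups. Among 16 tested telocyte genes, 12 were higher, 1 was lower and 3 did not pass, with camera adjusted p = 4.5e-17 and adjusted p = 0.17 with an estimated correlation. They held Bmp5 (2.32, 2932 ± 334 against 596 ± 156 (SD, n = 3 each)), Bmp7 (3.66), Wnt5a (3.26, chromosome 14, 28504750 to 28527447) and the endothelin receptor Ednrb (4.39), while Frzb, a secreted Wnt inhibitor, was lower (-1.21) and Gli1, a Hedgehog target, had 0.32 (adjusted p = 0.69). Of 18 genes of Cd34-positive fibroblasts, 0 were higher, 13 were lower and 5 did not pass, with camera adjusted p = 1.3e-16 and adjusted p = 0.18 with an estimated correlation. The lower members included Gsn, the actin-severing protein gelsolin (-2.60, 8686 ± 4492 against 47625 ± 5015 (SD, n = 3 each)), Clec3b (-1.55), Fbln1 (-1.38) and complement C3 (-2.54), and Dpt did not pass (-0.91, adjusted p = 0.25). Smooth muscle and myofibroblast genes gave 5 higher, 1 lower and 10 not past the threshold of 16, among them the myosin light chain kinase Mylk (2.71), Acta2, Myl9 (1.83) and Tagln (1.72), with Hhip lower (-1.18). Their camera adjusted p = 0.021, and adjusted p = 0.48 with an estimated correlation.

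Signals to the epithelium were divided between the populations. Of 14 BMP and related ligands, 5 were higher, 3 were lower and 6 did not pass (camera adjusted p = 0.017, adjusted p = 0.21 with an estimated correlation). Bmp2 (2.73, 3525 ± 926 against 551 ± 213 (SD, n = 3 each)), Bmp5, Bmp7 and Bmp3 were higher, Tgfb3 (-1.75) and Gdf10 (-3.69) were lower, and Bmp4 had 0.29 (adjusted p = 0.73). BMP antagonists gave 3 higher, 2 lower and 6 not past the threshold of 11 (camera adjusted p = 0.13), with Nbl1 (2.16), Twsg1 (1.41) and Fst (1.89) higher and Grem1 lower. Of 8 Wnt ligands, Wnt5a was higher, Wnt2b (-1.97), Wnt9a (-1.45) and Wnt2 (-2.76) were lower and 4 did not pass (camera adjusted p = 0.18). Secreted Wnt inhibitors gave 1 higher, 5 lower and 3 not past the threshold of 9, with Sfrp1 (-1.40), Frzb, Apcdd1 (-1.74) and Sfrp2 lower against Wif1 higher. The median of that list was -1.21 and its mean -0.05, and camera gave adjusted p = 0.12. The R-spondin Rspo3, which enhances Wnt signalling, was lower (-2.01, adjusted p = 0.0072), and Rspo1 had -0.09 (adjusted p = 0.95). Growth factors of the EGF, FGF, HGF and IGF families gave 4 higher, 1 lower and 13 not past the threshold of 18, with Nrg1 (3.76) and Fgf9 (2.40) higher and Fgf2 (-1.2) lower. Hedgehog pathway genes gave 2 higher, 2 lower and 6 not past the threshold of 10, with the receptor Ptch1 (1.26) higher.

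Matrix and vessel genes moved in both directions. Collagens gave 5 higher, 3 lower and 20 not past the threshold of 28, with Col14a1 (-2.28) and Col15a1 (-1.53) lower and the highest-read members Col3a1 (0.24) and Col1a1 (-0.11) not past. Matrix enzymes gave 2 higher, 2 lower and 21 not past the threshold of 25, with Plau, urokinase, higher (3.52) and Timp3 (-1.06) and Loxl1 (-1.26) lower. The basement membrane list gave 2 higher, 1 lower and 10 not past the threshold of 13. The laminin genes Lamb1 (1.16) and Lama5 (1.56) were higher and Lamb2 lower (-1.5). Secreted vessel factors gave 4 higher, 4 lower and 14 not past the threshold of 22, with Vegfa (1.79) and Sema3f (3.19) higher and Sema3c (-1.6) and Serpinf1 (-2.35) lower. Cytokines and chemokines gave 1 higher, 7 lower and 22 not past the threshold of 30 (camera adjusted p = 0.0070, adjusted p = 0.54 with an estimated correlation), with Cxcl14 higher (2.76) and Ccl2 (-1.67), Vcam1 (-1.15) and Ccl11 (-2.04) lower. Cell cycle genes gave 2 higher, 0 lower and 23 not past the threshold of 25 (camera adjusted p = 0.0031, adjusted p = 0.21 with an estimated correlation), and 7 higher and 0 lower adjusted over the list alone.

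Markers of other cell types were measured in both sorts. Immune genes gave 0 higher, 3 lower and 10 not past the threshold of 13 (camera adjusted p = 0.017, adjusted p = 0.50 with an estimated correlation), and the lower ones were the plasma cell genes Jchain (-3.54, 182 ± 189.6 against 1906 ± 1757 (SD, n = 3 each)) and Mzb1, and Cd52 (-3.17). Endothelial genes gave 0 higher, 2 lower and 11 not past the threshold of 13, pericyte genes 1 higher, 0 lower and 11 not past the threshold of 12, and genes of interstitial cells of Cajal 2 higher, 1 lower and 1 not past the threshold of 4, with Ano1 (2.66) and Etv1 (1.56) higher and Kit (-2.43) lower. Glia and neuron genes (5 tested), epithelial genes (11), erythroid genes (4), mesothelial genes (1) and interferon-stimulated genes (31) had 0 members past the threshold in limma, where 2312 of all genes had an unadjusted p under 0.05. Dissociation and heat-shock genes gave 0 higher, 1 lower and 23 not past the threshold of 24 (camera adjusted p = 0.044, adjusted p = 0.71 with an estimated correlation). Genes of the mitochondrial genome were in 0 of the tables. The count of 798 fell by more than 1.5 times without GFP-negative library 2 (461), GFP-positive library 1 (514) or GFP-positive library 3 (454), and equal totals gave 457 higher and 365 lower. In simulated data with the median spread of these libraries, 52.1% of 2-fold and 93% of 4-fold changes were recovered.

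The same contrast was then made in DSS-treated mice, to ask whether the 2 populations still differ in the injured colon. Here 12 of 16 telocyte genes were higher in GFP-positive cells (adjusted p = 0.20 with an estimated correlation) and 14 of 17 genes of Cd34-positive fibroblasts lower (adjusted p = 0.17 with an estimated correlation). Procr stood at 5385 ± 147 against 674 ± 140.3 (SD, n = 3 each) (3.02, adjusted p = 9.2e-08), Foxl1 at 262 ± 28.9 against 21.3 ± 5.51 (SD, n = 3 each) (3.58, adjusted p = 9.6e-08), Pdgfra at 1.51 (adjusted p = 3.6e-05) and Acta2 at 1.48 (adjusted p = 0.00031). Cd34 was lower at 215 ± 36.7 against 1286 ± 23.4 (SD, n = 3 each) (-2.59, adjusted p = 1.7e-07). Col6a1 did not pass (0.30, adjusted p = 0.51).

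Of 12570 genes tested with limma, 2152 passed, 1033 higher and 1119 lower, where equal totals gave 1203 and 920. The largest increases were in Wif1 (7.10, 267 ± 71.02 against 2 ± 3.46 (SD, n = 3 each)), Bmp3 (5.96), Sox6 (5.25), Bean1 (4.87), the histamine receptor Hrh1 (4.84) and Spag5 (4.80). The largest decreases were in Chodl (-4.95), Cntn1 (-4.90), Gdf10 (-4.69), Grem1 (-4.41, 150 ± 71.5 against 2974 ± 318 (SD, n = 3 each)), Foxp2 (-4.18) and Igfbp6 (-3.98). Telocyte genes gave 12 higher, 1 lower and 3 not past the threshold of 16 (camera adjusted p = 1.2e-14, adjusted p = 0.20 with an estimated correlation), among them Bmp5 (2.77), Wnt5a (3.57) and Bmp7 (3.94). Genes of Cd34-positive fibroblasts gave 1 higher, 14 lower and 2 not past the threshold of 17 (camera adjusted p = 4.7e-16, adjusted p = 0.17 with an estimated correlation), with C3 at 1517 ± 103 against 12852 ± 2050.3 (SD, n = 3 each) (-3.07), Gsn (-1.95) and Fbln1 (-1.86) lower.

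Cell cycle genes were higher in GFP-positive cells of the DSS colon, with 17 higher, 0 lower and 11 not past the threshold of 28 (camera adjusted p = 3.5e-09, adjusted p = 0.20 with an estimated correlation). Top2a, a DNA topoisomerase, had 1.67, the mitotic kinase Plk1 2.22 and Birc5, or survivin, 1.46, while Pcna had -0.16 (adjusted p = 0.69). Pericyte genes gave 8 higher, 1 lower and 3 not past the threshold of 12 (camera adjusted p = 0.0018, adjusted p = 0.37 with an estimated correlation), with the vessel marker Rgs5 (0.98) and the channel genes Abcc9 (0.91) and Kcnj8 (1.38) higher. Cytokines and chemokines were lower as a list, with 3 higher, 13 lower and 18 not past the threshold of 34 (camera adjusted p = 3.9e-05, adjusted p = 0.21 with an estimated correlation). Ccl2, which attracts monocytes, was read at 2323 ± 816 against 7980.3 ± 2553 (SD, n = 3 each) (-1.78), Il6 had -2.32, Vcam1 -2.02 and Cxcl5, which attracts neutrophils, -1.46. Basement membrane genes gave 5 higher, 1 lower and 6 not past the threshold of 12, with the laminin gene Lamb1 at 18845 ± 1181 against 8465 ± 1565 (SD, n = 3 each) (1.17).

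Secreted factors differed as well. BMP ligands gave 7 higher, 3 lower and 5 not past the threshold of 15 (camera adjusted p = 0.016, adjusted p = 0.27 with an estimated correlation) and BMP antagonists 2 higher, 7 lower and 3 not past the threshold of 12 (camera adjusted p = 0.015, adjusted p = 0.29 with an estimated correlation), with Fstl1 (-1.2) and Chrdl1 (-3.07) lower beside Grem1. Wnt inhibitors gave 1 higher, 5 lower and 2 not past the threshold of 8 (camera adjusted p = 0.0019, adjusted p = 0.20 with an estimated correlation), with Sfrp1 at 669 ± 36.5 against 6983 ± 540.1 (SD, n = 3 each) (-3.38). Rspo3 (-3.32) and Rspo2 (-3.51) were lower and Rspo1 had -1.15 (adjusted p = 0.053). Growth factors gave 2 higher, 7 lower and 8 not past the threshold of 17, with Fgf9 higher (3.66) and the keratinocyte growth factor Fgf7 (-2.34), Fgf10 (-1.45) and Igf1 (-0.75) lower. Collagens gave 9 higher, 7 lower and 10 not past the threshold of 26, with Col3a1 (-1.49) and Col1a1 (-1.03) lower and Col6a2 higher (1.02), and matrix enzymes 7 higher, 8 lower and 12 not past the threshold of 27. Epithelial genes gave 0 higher, 6 lower and 6 not past the threshold of 12 (camera adjusted p = 0.0013, adjusted p = 0.41 with an estimated correlation), glia and neuron genes 0 higher, 2 lower and 4 not past the threshold of 6 (camera adjusted p = 0.016, adjusted p = 0.30 with an estimated correlation), and all 3 tested mesothelial genes were lower. With a log2 fold change of at least 1 required, 1364 genes passed, and without DSS GFP-positive library 1 the count was 1431.

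The overlap of the 2 colon contrasts was tested over genes, in conditions that share no library. Of 12238 genes tested in both, 302 were higher in GFP-positive cells in both against 30.7 expected by chance, and 324 were lower in both against 32.7 (Fisher exact test, odds ratios 63.9 and 88.3). Only 2 genes passed in opposite directions. The Pearson correlation of log2 fold changes was 0.70 across genes, and genes are not independent replicates.

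**Figure D2:**
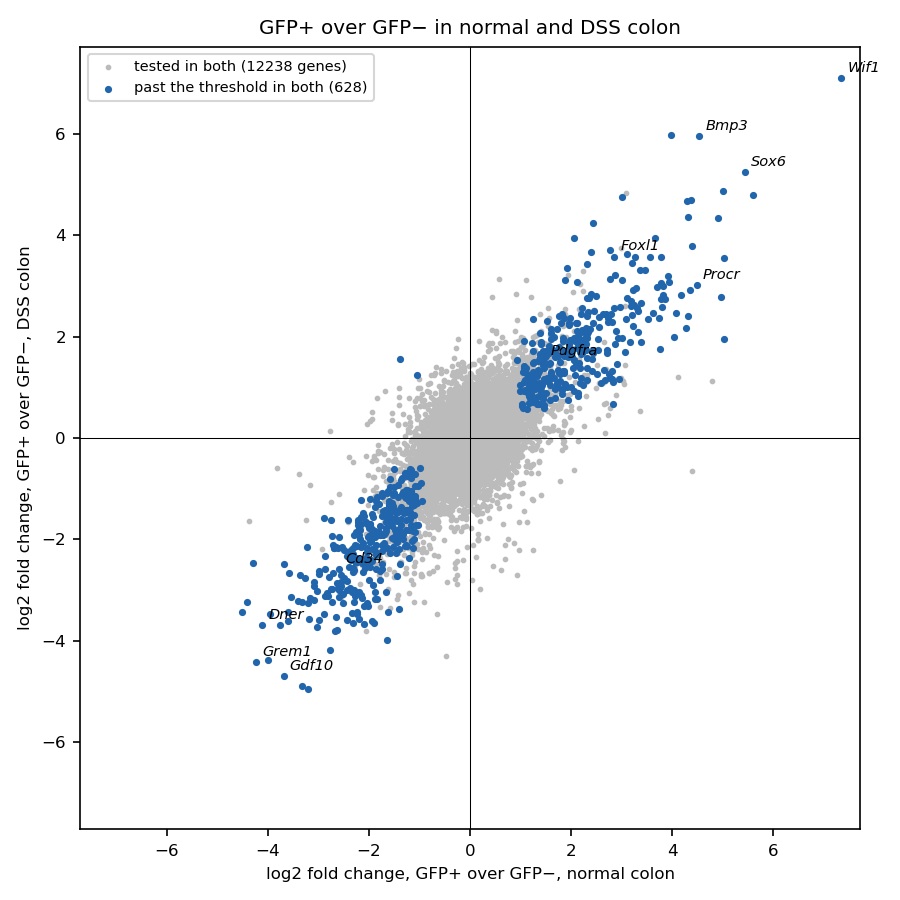
Log2 fold changes of GFP-positive over GFP-negative colon cells in normal mice (x axis) and DSS-treated mice (y axis), 1 point per gene tested in both. Coloured genes passed the threshold in both conditions.

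How the GFP-positive cells respond to DSS was asked next, in tables that hold normal and DSS libraries on 1 scale. Of the cytokine and chemokine genes 21 of 34 rose (adjusted p = 0.17 with an estimated correlation). Of the interferon-stimulated genes 19 of 31 did (adjusted p = 0.21 with an estimated correlation). Saa3, a serum amyloid A protein of the acute phase, rose from 11 ± 1.73 (SD, n = 3) to 4398 ± 639 (SD, n = 3) (8.52, adjusted p = 2.0e-11, chromosome 7, 46711998 to 46715700). Procr (0.47, adjusted p = 0.12), Pdgfra (0.39, adjusted p = 0.17), Foxl1 (-0.24, adjusted p = 0.44) and Acta2 (-0.65, adjusted p = 0.068) did not pass. Col6a1 fell from 1988 ± 414 (SD, n = 3) to 836 ± 94.7 (SD, n = 3) (-1.23, adjusted p = 0.0020) and Cd34 from 599 ± 93.6 (SD, n = 3) to 252 ± 42.5 (SD, n = 3) (-1.25, adjusted p = 0.0017).

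Of 12976 genes tested with limma, 2555 passed, 1328 higher and 1227 lower after DSS. Beside Saa3 the largest increases were in Olfr94 (7.68), Cxcl5 (7.16) and Ubd (7.07), a ubiquitin-like protein induced by interferon. Lcn2, an iron-binding antibacterial protein, and Hp, haptoglobin, were listed at 0 in all normal GFP-positive libraries and at 566 ± 328 (SD, n = 3) and 290 ± 233 (SD, n = 3) after DSS. Large decreases were found in Igfbp6 (-4.52), Tppp3 (-3.71), C1qtnf3 (-2.90), Pcolce2 (-2.84) and caveolin Cav1 (-2.56). Of 34 cytokine and chemokine genes 21 rose and 0 fell, with a median log2 fold change of 2.30 (camera adjusted p = 1.4e-15, adjusted p = 0.17 with an estimated correlation). Ccl2 rose from 299 ± 105 (SD, n = 3) to 2724 ± 963 (SD, n = 3) (3.18), Cxcl1 by 2.27 and Cxcl10 by 2.51, and Cxcl12 had -0.28 (adjusted p = 0.42). Of 31 interferon-stimulated genes 19 rose and 0 fell (median 1.5, camera adjusted p = 1.2e-14, adjusted p = 0.21 with an estimated correlation), among them the major histocompatibility genes H2-K1 (1.5) and H2-D1 (1.98) and the GTPase Iigp1 (2.49).

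Cell cycle genes gave 14 higher, 1 lower and 13 not past the threshold of 28 (camera adjusted p = 1.8e-05, adjusted p = 0.21 with an estimated correlation), with Birc5 (2.23) and Top2a (1.68) higher and Pcna lower (-1.08). Pericyte genes gave 5 higher, 1 lower and 6 not past the threshold of 12 (camera adjusted p = 0.013, adjusted p = 0.24 with an estimated correlation), and Rgs5 rose from 123 ± 71.02 (SD, n = 3) to 1331 ± 248 (SD, n = 3) (3.55). Collagens gave 3 higher, 9 lower and 14 not past the threshold of 26 (camera adjusted p = 0.013, adjusted p = 0.21 with an estimated correlation): Col3a1 (-1.34), Col1a1 (-1.10) and Col6a2 (-0.80) fell and Col18a1 (2.46) rose. Genes of Cd34-positive fibroblasts gave 3 higher, 10 lower and 5 not past the threshold of 18 (camera adjusted p = 0.0038, adjusted p = 0.49 with an estimated correlation), with Gsn (-1.54), Dpt (-1.52) and Clec3b (-1.92) lower and C3 higher (1.42). Telocyte genes gave 1 higher, 2 lower and 13 not past the threshold of 16, Bmp5 with 0.54 (adjusted p = 0.071). Among signals, Bmp4 fell (-1.56, adjusted p = 0.00032), Grem1 rose (1.61, adjusted p = 0.012), Wif1 rose (0.84) and the growth factor Igf1 rose (1.53, adjusted p = 0.00019). Matrix enzymes gave 6 higher, 3 lower and 18 not past the threshold of 27, with Mmp3 (4.82) higher and Timp2 (-0.72) lower. Immune genes gave 5 higher, 0 lower and 13 not past the threshold of 18 (camera adjusted p = 0.0049, adjusted p = 0.42 with an estimated correlation), and the neutrophil gene S100a8 was read at 70.3 ± 56.1 (SD, n = 3) after DSS.

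With a log2 fold change of at least 1 required, 1538 genes passed. Without DSS GFP-positive libraries 1, 2 or 3 the count fell from 2555 to 1443, 1253 and 1569. Scaling the libraries to equal totals shifted the median of all genes to -0.13 and gave 991 genes higher and 1585 lower, where the authors' scaling gave 1328 and 1227.

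The GFP-negative cells were compared in the same way. Here 23 of 33 cytokine and chemokine genes rose (adjusted p = 0.21 with an estimated correlation) and 21 of 32 interferon-stimulated genes (adjusted p = 0.20 with an estimated correlation). So did Rspo3 and Rspo1 and 6 of 17 growth factors (adjusted p = 0.36 with an estimated correlation). Saa3 rose from 8 ± 7.81 (SD, n = 3) to 8086 ± 1439.7 (SD, n = 3) (10.13, adjusted p = 1.1e-06), and Rspo3 from 48.3 ± 15.04 (SD, n = 3) to 199.7 ± 46.5 (SD, n = 3) (2.04, adjusted p = 0.0015, chromosome 10, 29453109 to 29535867). Procr, low in normal GFP-negative cells, rose from 216 ± 81.6 (SD, n = 3) to 793 ± 167 (SD, n = 3) (1.93, adjusted p = 0.0034), and Cd34 fell (-1.26, adjusted p = 0.021). Pdgfra (0.34), Acta2 (0.02), Col6a1 (-1.04, adjusted p = 0.070) and Foxl1 (-1.0, adjusted p = 0.070) did not pass.

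Of 13025 genes tested with limma, 1341 passed, 785 higher and 556 lower after DSS. The largest increases with reads in both conditions were in Saa3, Hp (9.08), Cxcl5 (7.56), Lcn2 (7.34) and Ubd (6.99). Reg3b, an antibacterial lectin of the epithelium, was listed at 0 in all normal GFP-negative libraries and at 185 ± 142 (SD, n = 3) after DSS. Epithelial genes stood at a median of 1.47% of the unsorted level in normal and 4.50% in DSS GFP-negative cells. Reg3b is therefore not shown to rise in mesenchymal cells. The largest decreases were in Ndufb11 (-3.22), Crip1 (-3.01), Enpp3 (-2.52), Pcolce2 (-2.49), Stmn2 (-2.44) and Aspn (-2.41). Of 33 cytokine and chemokine genes 23 rose and 0 fell (median 2.08, camera adjusted p = 1.6e-21, adjusted p = 0.21 with an estimated correlation), among them Ccl2 (3.29), Vcam1 (2.71), Il11 (4.15) and Il6 (2.05). Of 32 interferon-stimulated genes 21 rose and 0 fell (median 1.80, camera adjusted p = 8.7e-18, adjusted p = 0.20 with an estimated correlation), with the transcription factor Irf1 (2.33), H2-K1 (2.10) and Iigp1 (3.36).

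Growth factors gave 6 higher, 0 lower and 11 not past the threshold of 17 (camera adjusted p = 0.026, adjusted p = 0.36 with an estimated correlation): Ereg, a ligand of the EGF receptor, rose from 416 ± 198 (SD, n = 3) to 3184 ± 374 (SD, n = 3) (3.07), Nrg1 by 2.69, Igf1 by 1.22 and Fgf7 by 1.6. Of the 3 tested R-spondins, Rspo3 and Rspo1 (1.37) rose and Rspo2 had 1.43 (adjusted p = 0.17). BMP antagonists gave 5 higher, 2 lower and 5 not past the threshold of 12, with Grem1 (1.80) and Chrdl2 (4.09) higher and Fstl3 (-0.93) and Chrd (-1.17) lower. Wnt ligands gave 0 higher, 2 lower and 6 not past the threshold of 8 (camera adjusted p = 0.020, adjusted p = 0.32 with an estimated correlation), with Wnt2 (-1.57) and Wnt5b (-0.93) lower. Matrix enzymes gave 8 higher, 1 lower and 18 not past the threshold of 27 (camera adjusted p = 0.0011, adjusted p = 0.22 with an estimated correlation), and collagens 1 higher, 4 lower and 21 not past the threshold of 26, with Col14a1 (-1.34) and Col15a1 (-1.42) lower, Col18a1 (1.89) higher and Col3a1 at 0.38 (adjusted p = 0.53). Genes of Cd34-positive fibroblasts gave 2 higher, 8 lower and 8 not past the threshold of 18 (camera adjusted p = 0.020, adjusted p = 0.21 with an estimated correlation), with Gsn lower (-2.18) and C3 higher (1.95).

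Epithelial genes had 0 of 15 members past the threshold in limma but a camera adjusted p = 0.015 in the direction of DSS, and adjusted p = 0.63 with an estimated correlation. Carried-over epithelium was not separated from this shift. Immune genes gave 2 higher, 0 lower and 15 not past the threshold of 17 (camera adjusted p = 0.032, adjusted p = 0.55 with an estimated correlation), S100a8 at 5.88 and S100a9 at 5.70. Without GFP-negative library 2, DSS GFP-negative library 2 or DSS GFP-negative library 3 the count of 1341 fell to 704, 360 and 477, and with all 4 sorted colon groups in 1 fit it was 2068. Equal totals shifted the median of all genes to -0.14 and gave 612 higher and 776 lower, where the authors' scaling gave 785 and 556.

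Both responses were compared over 12419 genes tested in both. 451 rose in both populations against 77.2 expected by chance, and 295 fell in both against 50.7 (Fisher exact test, odds ratios 19.8 and 15.3), with 2 in opposite directions. Log2 fold changes had a Pearson correlation of 0.73 across genes, which are not independent replicates. The library numbers of normal and DSS colon samples do not overlap, so a difference between library series would move both responses alike.

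**Figure D3:**
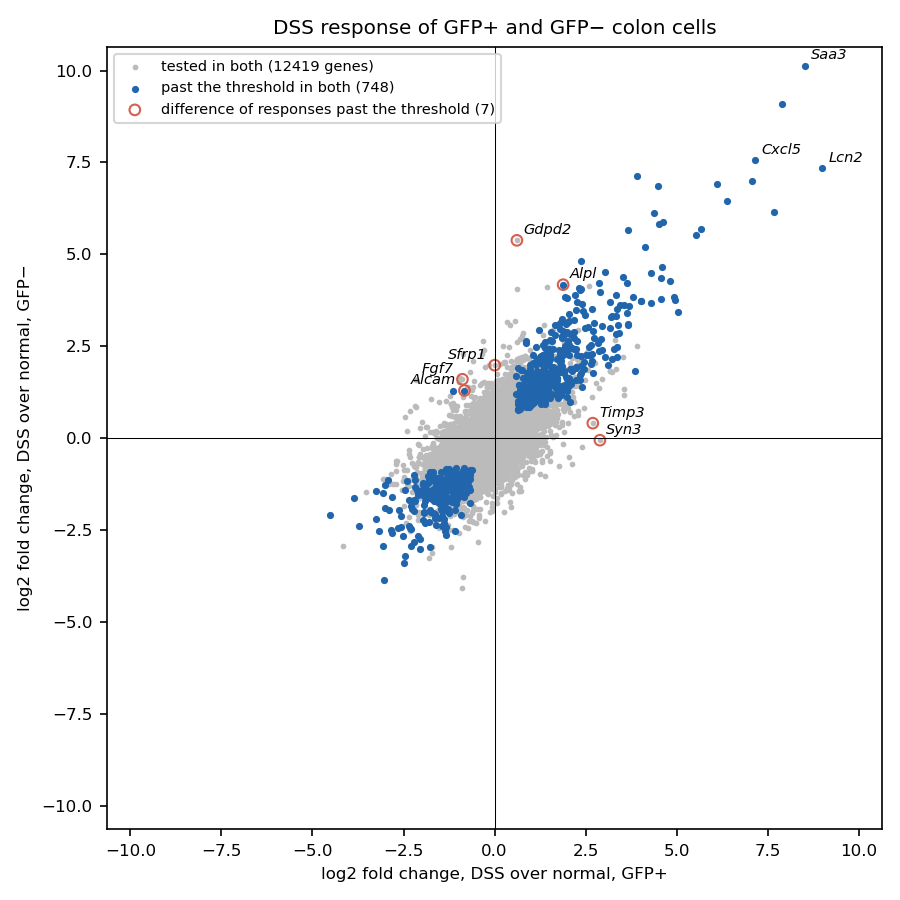
Log2 fold change of DSS over normal in GFP-positive (x axis) and GFP-negative (y axis) colon cells, 1 point per gene tested in both. Circled genes differed between the 2 responses at an adjusted p of 0.05.

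Whether a gene responded differently in the 2 populations was tested directly, as the DSS response of GFP-positive cells minus that of GFP-negative cells in the 12 sorted colon libraries. Of 13488 genes, 7 passed in limma, 2 with the more positive response in GFP-positive cells and 5 in GFP-negative cells, and 1081 had an unadjusted p under 0.05. Sfrp1, a secreted Wnt inhibitor, went from 806 ± 256 (SD, n = 3) to 784 ± 43.03 (SD, n = 3) in GFP-positive cells and from 2087 ± 293 (SD, n = 3) to 8211 ± 620.4 (SD, n = 3) in GFP-negative cells, a difference of -1.98 (adjusted p = 0.042, chromosome 8, 23411502 to 23449632). Fgf7, a growth factor for epithelial cells, rose only in GFP-negative cells (1.6, with -0.88 in GFP-positive cells), a difference of -2.48 (adjusted p = 0.046, chromosome 2, 126034658 to 126091185). Alpl, an alkaline phosphatase (-2.29, adjusted p = 0.021, chromosome 4, 137741733 to 137796384), the cell adhesion gene Alcam (-2.12, adjusted p = 0.015, chromosome 16, 52248996 to 52454074) and Gdpd2 (-4.77, adjusted p = 0.0069, chromosome X, 100729873 to 100738895) also had the more positive response in GFP-negative cells. Timp3, an inhibitor of matrix proteases, rose from 1093 ± 51.8 (SD, n = 3) to 7103 ± 409 (SD, n = 3) in GFP-positive cells, with 2301 ± 335 (SD, n = 3) and 3071 ± 677 (SD, n = 3) in GFP-negative cells, a difference of 2.29 (adjusted p = 0.0069, chromosome 10, 86300372 to 86349506). Syn3 (2.95, adjusted p = 0.0027, chromosome 10, 86055125 to 86498896) holds Timp3 within its bounds on the opposite strand, and it is uncertain whether the counting separated the 2 genes.

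Procr had a difference of -1.46 (adjusted p = 0.35), Grem1 of -0.19 and Rspo3 of -1.35 (adjusted p = 0.54), so different responses were not shown for these genes. Camera on the difference gave epithelial genes a median of -1.5 (adjusted p = 0.00079, adjusted p = 0.46 with an estimated correlation), growth factors -0.62 (adjusted p = 0.0036, adjusted p = 0.21 with an estimated correlation) and interferon-stimulated genes -0.47 (adjusted p = 0.0095, adjusted p = 0.47 with an estimated correlation). Wnt inhibitors had -0.30 (adjusted p = 0.017, adjusted p = 0.21 with an estimated correlation), BMP antagonists -0.37 (adjusted p = 0.027, adjusted p = 0.21 with an estimated correlation) and matrix enzymes -0.33 (adjusted p = 0.036, adjusted p = 0.27 with an estimated correlation). Cell cycle genes had 0.33 (adjusted p = 0.00049, adjusted p = 0.18 with an estimated correlation). The count of 7 became 3 without GFP-positive library 3 or DSS GFP-positive library 1, 4 without DSS GFP-positive library 2 or 3 or DSS GFP-negative library 1 or 2, 2 without DSS GFP-negative library 3 and 15 without GFP-negative library 1. In simulated data 24.2% of 2-fold and 89.9% of 4-fold differences were recovered.

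In the small intestine, cells with high GFP were compared with GFP-negative cells to ask whether the colon contrast is found there. Higher in high-GFP cells were 7 of 14 telocyte and 3 of 16 smooth muscle genes. Lower were 7 of 18 genes of Cd34-positive fibroblasts (adjusted p = 0.17 with an estimated correlation for each of the 3 lists). Bmp7 was read at 458 ± 65.2 against 8.67 ± 9.61 (SD, n = 3 each) (6.39, adjusted p = 0.027, chromosome 2, 172868012 to 172940321), Sox6 at 222 ± 135 against 1.67 ± 2.08 (SD, n = 3 each) (6.51, adjusted p = 0.0025) and Dio2, the deiodinase that activates thyroid hormone, at 420 ± 112 against 5.33 ± 4.16 (SD, n = 3 each) (6.23, adjusted p = 0.00050, chromosome 12, 90724554 to 90738438). Pdgfra was higher at 1926 ± 753 against 565 ± 136 (SD, n = 3 each) (1.73, adjusted p = 0.041). Pi16, a marker of adventitial fibroblasts, was lower at 17.7 ± 15.04 against 520 ± 152 (SD, n = 3 each) (-5.33, adjusted p = 0.027, chromosome 17, 29318877 to 29329413).

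Of 12412 genes tested with limma, 111 passed, 49 higher and 62 lower. This split turned to 36 and 22, 52 and 30, and 68 and 36 without GFP-negative libraries 1, 2 and 3, and was 4 and 20 without high-GFP library 3. With equal totals it was 58 higher and 50 lower. Trp53i11 (6.88), Kcnj8 (6.51) and Bmp3 (6.48) were among the largest increases, and Ccl21a (-5.37), a chemokine of lymphatic vessels, Vldlr (-4.96), Chodl (-4.92) and Gdf10 (-4.41) among the largest decreases. Mmrn1, a gene of lymphatic endothelium, was listed at 0 in all high-GFP libraries and at 169 ± 192 (SD, n = 3) in GFP-negative ones. Endothelial genes stood at a median of 38.1% of the unsorted level in GFP-negative and 12.2% in high-GFP cells. Vessel genes such as Ccl21a and Mmrn1 are therefore not shown to differ between mesenchymal cells. Procr stood at 252 ± 59.1 against 22.3 ± 20.4 (SD, n = 3 each) and did not pass (4.57, SE 1.49, adjusted p = 0.37), nor did Cd34 (-1.63, adjusted p = 0.070), Acta2 (2.06, adjusted p = 0.23), Foxl1 (2.66, adjusted p = 0.40) and Col6a1 (0.11, adjusted p = 0.95). Telocyte genes gave 7 higher, 0 lower and 7 not past the threshold of 14 (camera adjusted p = 6.1e-11, adjusted p = 0.17 with an estimated correlation), with Bmp5 (3.79), Ednrb (5.90) and Wnt5a (2.91). Smooth muscle genes gave 3 higher, 0 lower and 13 not past the threshold of 16 (camera adjusted p = 8.0e-11, adjusted p = 0.17 with an estimated correlation), with Mylk (2.27), Tagln (2.55) and Myl9 (1.97), and 9 higher and 0 lower adjusted over the list alone. Genes of Cd34-positive fibroblasts gave 0 higher, 7 lower and 11 not past the threshold of 18 (camera adjusted p = 3.3e-16, adjusted p = 0.17 with an estimated correlation), with Fbln1 (-1.77) and Mfap5 (-2.01) lower, and Gsn at -1.05 (adjusted p = 0.20).

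Pericyte genes gave 2 higher, 0 lower and 10 not past the threshold of 12 (camera adjusted p = 6.9e-07, adjusted p = 0.17 with an estimated correlation) and BMP ligands 3 higher, 1 lower and 11 not past the threshold of 15 (camera adjusted p = 0.022, adjusted p = 0.23 with an estimated correlation). Dissociation and heat-shock genes were lower in high-GFP cells, with 0 higher, 7 lower and 17 not past the threshold of 24 (camera adjusted p = 3.0e-17, adjusted p = 0.21 with an estimated correlation): Junb (-2.36, chromosome 8, 84974484 to 84978718), Egr1 (-1.85), Jun (-1.81) and Zfp36 (-3.24) were lower. Immune genes had 0 of 19 past the threshold in limma (camera adjusted p = 2.3e-05, adjusted p = 0.24 with an estimated correlation), where 1311 of all genes had an unadjusted p under 0.05, and endothelial genes gave 0 higher, 1 lower and 15 not past the threshold of 16 (camera adjusted p = 0.00088, adjusted p = 0.46 with an estimated correlation). Spread was wider here than in the colon, and 11.5% of simulated 2-fold and 76.8% of 4-fold changes were recovered. The count of 111 was 58 without GFP-negative library 1, 59 without high-GFP library 1, 24 without high-GFP library 3 and 245 with all 4 groups in 1 fit.

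With the normal colon contrast, 34 genes were higher in both against 1.36 expected by chance and 37 were lower in both against 1.87 (Fisher exact test, odds ratios 88.3 and 55.5), with 0 in opposite directions over 11313 genes. Across these genes the Pearson correlation of log2 fold changes was 0.38, and genes are not independent replicates. In the normal colon, the DSS colon and the small intestine alike, 34 genes were higher, among them Sox6, Bmp3, Bmp5, Bmp7, Bean1, Ednrb, Wnt5a and Pdgfra. In all 3 contrasts 35 were lower, among them Grem1, Gdf10, Chodl, Igfbp6 and Pi16.

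Low-GFP cells of the small intestine were compared with the same GFP-negative cells. Of the telocyte genes 0 passed in limma, and the calls depended strongly on single libraries. Pdlim1, a cytoskeletal adaptor, was read at 829 ± 121 against 173 ± 37.6 (SD, n = 3 each) (2.27, adjusted p = 0.0070), and the pericyte gene Rgs5 at 6142 ± 1354 against 1935 ± 386 (SD, n = 3 each) (1.66, adjusted p = 0.028). Of the epithelial genes Fabp6, the ileal bile acid binding protein, was lower at 3 ± 2.65 against 1023 ± 667 (SD, n = 3 each) (-8.13, adjusted p = 0.0021, chromosome 11, 43596049 to 43601540) and Reg3b at 0.333 ± 0.577 against 1377 ± 1408 (SD, n = 3 each) (-9.31, adjusted p = 0.0028, chromosome 6, 78370657 to 78373466). Ccl21a was listed at 0 in all low-GFP libraries and at 221 ± 214 (SD, n = 3) in GFP-negative ones. Endothelial genes stood at a median of 7.82% of the unsorted level in low-GFP and 38.1% in GFP-negative cells, so Ccl21a is not shown to differ between mesenchymal cells.

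Of 12445 genes tested with limma, 84 passed, 14 higher and 70 lower, and 2100 had an unadjusted p under 0.05. Without GFP-negative library 2 the split was 22 higher and 14 lower, with 16 of the 84 among them. Without GFP-negative library 3 it was 18 and 24. Of simulated 2-fold changes 22.7% were recovered, so a low count of calls does not mean few differences. The heparanase Hpse (2.57), Snx9 (2.49), the axon guidance receptor Robo2 (2.12), Slc43a3 (2.03) and Pamr1 (1.96) were higher beside Pdlim1, and Mzb1 (-3.87), Chodl (-3.83) and Pi16 (-3.68) were lower. Pdgfra (0.30, adjusted p = 0.59), Procr (1.48, adjusted p = 0.60), Cd34 (-1.30, adjusted p = 0.081), Col6a1 (0.65, adjusted p = 0.36) and Acta2 (-0.34, adjusted p = 0.79) did not pass, and Foxl1 was below the level for testing. Genes of Cd34-positive fibroblasts gave 0 higher, 3 lower and 15 not past the threshold of 18 (camera adjusted p = 1.7e-05, adjusted p = 0.24 with an estimated correlation). Dissociation genes gave 0 higher, 5 lower and 19 not past the threshold of 24 (camera adjusted p = 6.6e-09, adjusted p = 0.24 with an estimated correlation), with Junb (-2.69), Jun (-1.32) and Zfp36 (-3.22) lower. Pericyte genes gave 1 higher, 0 lower and 10 not past the threshold of 11 (camera adjusted p = 0.0019, adjusted p = 0.23 with an estimated correlation). Immune genes gave 0 higher, 1 lower and 20 not past the threshold of 21 (camera adjusted p = 0.0026, adjusted p = 0.34 with an estimated correlation), and endothelial genes had 0 of 16 past the threshold in limma (camera adjusted p = 0.00040, adjusted p = 0.42 with an estimated correlation).

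The low-GFP contrast shared 22 lower genes with the normal colon contrast against 2.11 expected by chance (Fisher exact test, odds ratio 15.9), over 11310 genes. It shared 0 higher genes against 0.36 expected (adjusted p = 1), too few for the test to show an absence. In this overlap 3 genes passed in opposite directions. The count of 84 was 16, 36 and 42 without GFP-negative libraries 1, 2 and 3, 6 without low-GFP library 1 and 6 without low-GFP library 3. With a replicate block it was 43, with all 4 groups in 1 fit 130, with equal totals 44 and with voom 152.

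High-GFP and low-GFP cells were then compared directly, to ask whether the GFP level separates different cells. Higher in high-GFP cells were 6 of 16 smooth muscle genes and 6 of 14 telocyte genes (adjusted p = 0.17 with an estimated correlation for each list). Acta2 was read at 2382 ± 886 against 442 ± 147 (SD, n = 3 each) (2.40, adjusted p = 0.0083), Tagln at 997 ± 209.7 against 143 ± 14.4 (SD, n = 3 each) (2.77, adjusted p = 0.0015) and Dio2 at 420 ± 112 against 5 ± 4.58 (SD, n = 3 each) (6.64, adjusted p = 0.0064). Bmp7 (3.88, adjusted p = 0.0011) and Ednrb (4.16, adjusted p = 0.0015) were higher as well. Pcolce2 (-2.55, adjusted p = 0.0096), an enhancer of collagen processing, was lower.

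Of 12226 genes tested with limma, 47 passed, 45 higher and 2 lower. Another split of the same libraries into groups of 3 gave 40 genes, so the count of 47 is not far above that of a wrong grouping. Wif1 (4.92), Bean1 (4.67), the calcium store protein Casq2 (4.46), Sv2b (4.44) and Sox6 (4.21) had the largest increases after Dio2. Smooth muscle genes gave 6 higher, 0 lower and 10 not past the threshold of 16 (camera adjusted p = 1.7e-17, adjusted p = 0.17 with an estimated correlation), with Tpm2 (2.70), Myl9 (2.70) and Myh11 (2.87) higher and Mylk at 1.24 (adjusted p = 0.32). Telocyte genes gave 6 higher, 0 lower and 8 not past the threshold of 14 (camera adjusted p = 2.2e-11, adjusted p = 0.17 with an estimated correlation), and genes of Cd34-positive fibroblasts 0 of 18 past the threshold in limma (camera adjusted p = 4.3e-06, adjusted p = 0.21 with an estimated correlation), where 942 of all genes had an unadjusted p under 0.05. Wnt5a (2.30) and Wnt4 (2.51) were higher among 4 tested Wnt ligands. Pdgfra (1.43, adjusted p = 0.12), Procr (3.09, adjusted p = 0.16), Cd34 (-0.33, adjusted p = 0.82), Foxl1 (2.31, adjusted p = 0.63) and Col6a1 (-0.54, adjusted p = 0.74) did not pass. The count of 47 was 25, 28 and 14 without high-GFP libraries 1, 2 and 3. With a replicate block it was 91, 72 higher and 19 lower. With all 4 groups in 1 fit it was 21.

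**Figure D4:**
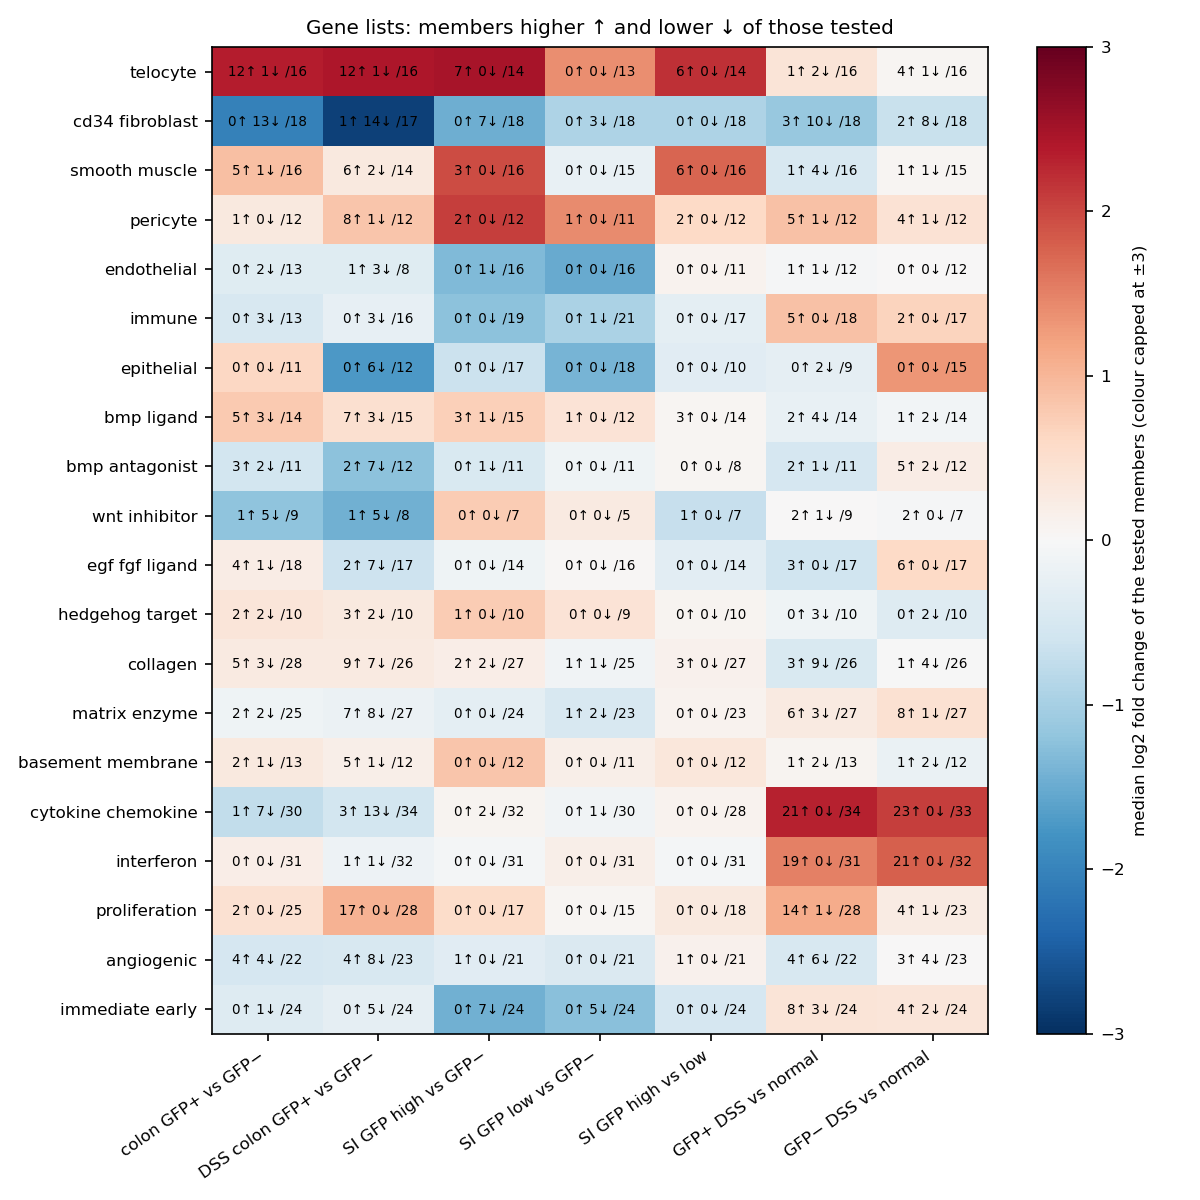
Median log2 fold change of gene lists in the 7 comparisons between sorted groups, with the numbers of members higher and lower at an adjusted p of 0.05. Lists with at least 5 tested members in all of these comparisons are shown. Lists were fixed before the data were seen.

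Comparison with unsorted cells asked what the sorts enriched against the whole preparation. Lower in GFP-positive cells of the normal colon were 26 of 28 immune genes (adjusted p = 0.17 with an estimated correlation) and 25 of 27 epithelial genes (0.29). So were 14 of 17 endothelial genes (0.17) and 6 of 6 red blood cell genes (0.21). Their median levels were 1.33% of the unsorted level for immune, 1.28% for epithelial and 5.30% for endothelial genes. Collagens were higher (13 higher, 0 lower and 13 not past the threshold of 26, camera adjusted p = 6.8e-08, adjusted p = 0.21 with an estimated correlation), and so were telocyte genes (14 of 16, camera adjusted p = 2.7e-10, adjusted p = 0.17 with an estimated correlation). Procr (2.40), Pdgfra (2.72), Foxl1 (2.57) and Col6a1 (1.84, 2369 ± 486 against 674 ± 208 (SD, n = 3 each)) were higher, and Acta2 (-0.16, adjusted p = 0.78) and Cd34 (0.33, adjusted p = 0.61) did not pass. The antigen presentation gene H2-Aa (-8.18) and the goblet and enterocyte gene Guca2a (-7.73) were the largest decreases, and Ccdc3 (3.58), Slc6a11 (3.58) and Cacng7 (3.58) the largest increases. Gpr183 was listed at 0 in all GFP-positive libraries and at 303 ± 324 (SD, n = 3) in unsorted ones. In limma 3197 of 14649 genes passed, 1131 higher and 2066 lower, and without GFP-positive libraries 1, 2 and 3 the counts were 2070, 2069 and 2020.

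GFP-negative cells of the normal colon had 26 of 28 immune genes lower (adjusted p = 0.17 with an estimated correlation) and 25 of 27 epithelial genes (adjusted p = 0.29 with an estimated correlation). Their immune genes stood at a median of 2.77% and their epithelial genes at 1.47% of the unsorted level. Genes of Cd34-positive fibroblasts were enriched (12 higher, 1 lower and 5 not past the threshold of 18, camera adjusted p = 4.8e-06, adjusted p = 0.21 with an estimated correlation), with Cd34 (2.93, 4463 ± 1471 against 632 ± 363 (SD, n = 3 each)) and Pi16 (3.48) higher beside Dner (2.99) and fibrillin Fbn1 (2.94). Procr (-2.09) and Acta2 (-2.31) were lower, and so were Dmbt1 (-7.86), H2-Aa (-7.70) and haemoglobin Hba-a2 (-7.62). Pdgfra (1.25) and Col6a1 (1.34) were higher and Foxl1 had -0.29 (adjusted p = 0.68). In limma 2753 of 14617 genes passed, 849 higher and 1904 lower, and without unsorted libraries 2 or 3 or GFP-negative libraries 1 or 2 the counts were 1731, 1690, 1831 and 1554.

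After DSS, 27 of 28 immune and 25 of 25 epithelial genes were lower in GFP-positive cells, and 28 of 28 and 25 of 25 in GFP-negative cells. For the immune list these had adjusted p = 0.21 with an estimated correlation and 0.18, and for the epithelial list 0.19 and 0.24. Median levels were 1.54% and 2.06% of the unsorted level for immune genes and 1.203% and 4.50% for epithelial genes. In GFP-positive cells Procr (2.47), Pdgfra (2.78), Col6a1 (1.64), Foxl1 (3.62), Slc6a11 (4.38), Lrrc55 (4.34) and Wif1 (4.19) were higher, and Reg3b (-7.52) and Wfdc17 (-7.84) were lower. Acta2 had 0.11 (adjusted p = 0.73) and Cd34 -0.38 (adjusted p = 0.26). In GFP-negative cells Cd34 (2.21), Pdgfra (1.28), Col6a1 (1.34), Clec3b (3.00), Fmo2 (2.92) and Cpxm1 (3.18) were higher and Acta2 (-1.37) was lower, and Procr had -0.55 (adjusted p = 0.12). Pancreatic amylase genes were lower in both, Amy2a2 by -7.85 and -8.36, but near-identical copies of these genes make it uncertain which copy was read. In limma 5070 of 13662 genes passed for GFP-positive cells (2165 higher and 2905 lower) and 4509 for GFP-negative cells (1871 and 2638, and 1378 and 3152 with equal totals).

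In the small intestine 28 of 30 immune genes were lower in high-GFP cells, 27 of 30 in low-GFP cells and 23 of 30 in GFP-negative cells than in unsorted cells (adjusted p = 0.17 with an estimated correlation, with 0.17 and 0.21 in the latter sorts). Epithelial genes were lower in 21 of 29, 24 of 29 and 12 of 28, at medians of 2.12%, 0.623% and 10.7% of the unsorted level (adjusted p = 0.21 with an estimated correlation, with 0.21 and 0.35 in the latter sorts). Endothelial genes stood at medians of 12.2%, 7.82% and 38.1%, and red blood cell genes at 11.5%, 26.01% and 19.5%. Of 26 tested collagens 22, 18 and 14 were higher in these sorts (adjusted p = 0.20 with an estimated correlation, with 0.22 and 0.17 in low-GFP and GFP-negative cells). Col6a1 (2.68, 3.23 and 2.57) and Cd34 (1.59, 1.92 and 3.22) were higher in high-GFP, low-GFP and GFP-negative cells. Pdgfra was higher in high-GFP (2.91) and low-GFP cells (1.48) and had 1.19 in GFP-negative cells (adjusted p = 0.052). Acta2 was higher in high-GFP cells (1.81). Procr had 0.11 in high-GFP cells (adjusted p = 0.86). In low-GFP libraries Procr was read at 24, 89 and 10 and in GFP-negative libraries at 27, 0 and 40, below the 239 and 220 of the unsorted libraries.

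The intestinal lectin Itln1 (-10.19) in low-GFP cells, the goblet cell gene Zg16 (-9.78 and -9.98), Reg3b (-8.66 and -10.34) in both GFP sorts and Mzb1 (-8.86) in high-GFP cells were the largest decreases. In GFP-negative cells these were defensins of Paneth cells, led by Defa22 (-10.00), a multigene family in which reads are hard to assign, and Adh1 (4.23), Inmt (5.74) and the prostaglandin receptor Ptgfr (4.51) were the largest increases. In high-GFP and low-GFP cells the largest increases were in genes best known from the liver, Cyp3a11 (7.68) and Cyp2c29 (8.13) in the first and Cyp2c29 (9.19) and the asialoglycoprotein receptor Asgr1 (8.76) in the second. Cyp2b10 was listed at 0 in the unsorted libraries and at 429 ± 362 (SD, n = 3) and 500 ± 182 (SD, n = 3) in high-GFP and low-GFP cells.

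In limma 2300 of 13369 genes passed for high-GFP cells (820 higher and 1480 lower), 3067 of 13434 for low-GFP cells (1227 and 1840) and 1543 of 13374 for GFP-negative cells (612 and 931). With 1 unsorted library left, where the spread comes from the sorted group alone, these counts fell to 0 and 2 in high-GFP cells (without unsorted libraries 2 and 3), 210 and 606 in low-GFP cells and 0 and 68 in GFP-negative cells. The split then turned, to 132 higher and 78 lower and 358 and 248 in low-GFP cells and to 49 and 19 in GFP-negative cells without unsorted library 3. In GFP-negative cells 1002 passed without GFP-negative library 1 and 845 with a replicate block. The medians of all genes were -0.14, -0.14 and -0.26 under the authors' scaling.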

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

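The random splits were chosen after the result was seen, and the test of the difference, the list tests and the contrasts of each tissue were planned.

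In the difference of DSS responses (GFP-positive minus GFP-negative colon cells) 7 genes passed: Syn3 (2.95), Timp3 (2.29), Alcam (-2.12), Alpl (-2.29), Fgf7 (-2.48), Gdpd2 (-4.77) and Sfrp1 (-1.98). In 100 splits of the libraries, the real one included, the highest other count was 1, and only the real one reached 7. The random splits mixed all 4 groups, so the sort and DSS differences entered the spread and lowered their counts. These splits therefore cannot show that the 7 genes are beyond chance. List medians of this difference were -1.504 for epithelial genes, -0.62 for growth factors, -0.47 for interferon-stimulated genes, -0.37 for BMP antagonists, -0.33 for matrix enzymes, -0.30 for Wnt inhibitors and 0.33 for cell cycle genes.

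Bmp6, Galnt15 and Ogn passed in opposite directions in the normal colon (GFP-positive over GFP-negative) and in low-GFP cells of the small intestine (over GFP-negative). The values were -1.06 and 1.96 for Bmp6, 2.15 and -2.14 for Galnt15, and 2.05 and -1.93 for Ogn. The difference between the tissues was not tested.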

How the results depend on the processing

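Counts of genes past the threshold are the results compared here. Rescaling, equal totals, voom and, in the colon, fits with all groups of a scale were chosen after the result was seen, and the others were planned. Leaving out 1 library at a time gave 454 to 888 genes for the normal colon contrast, 1431 to 2040 for the DSS colon contrast, 1253 to 2611 and 360 to 1882 for DSS against normal in GFP-positive and GFP-negative cells, and 2 to 15 for their difference. In the small intestine it gave 24 to 104 (high GFP), 6 to 76 (low GFP) and 14 to 52 (high against low). Against unsorted cells it gave 2020 to 4168 and 1554 to 3367 in the normal colon, 3925 to 5240 and 3305 to 4324 in the DSS colon, and 0 to 2524, 210 to 2983 and 0 to 1627 in the small intestine, where the counts of 0 are limma fits with 1 unsorted library left, so that the spread comes from the sorted group alone. The cause of these moves was not tested.

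A log2 fold change of at least 1 left 1364 genes in the DSS colon contrast and 1538 in the DSS response of GFP-positive cells. All groups of a scale in 1 fit gave 2068 for the DSS response of GFP-negative cells, 245 for high GFP, 130 for low GFP and 21 for high against low GFP. Low GFP against negative gave 44 with equal totals and 152 with voom. With an estimated correlation 0 of the 174 gene list calls were kept, a setting in which hardly any list could pass with so few libraries.

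Replicate numbers were checked as possible pairs. In no comparison was every correlation between same-numbered libraries over 0.1, so pairing by number was not shown. High against low GFP is open in this respect, since there every library correlated best with that of its own number. GFP-negative against unsorted cells of the DSS colon is open as well. Its correlations for numbers 1, 2 and 3 were 0.363, 0.0447 and 0.288, and a replicate block gave 5680 genes against 4509 without it. A replicate block gave 43 genes for low GFP against negative, 91 for high against low GFP, with correlations of 0.0777 to 0.230, and 845 for GFP-negative against unsorted small intestine, and changed no other count by more than 1.5 times.

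Of 1092 calls of named genes, 1085 were kept with median ratio rescaling, 1062 with equal totals, 1060 with a pseudocount of 0.5, 1069 with no filter, 1018 with a block and 1046 with voom. With all groups of a scale in 1 fit, 543 of 568 calls were kept where the scale held 3 groups and 452 of 517 where it held 4. Over all leave-one-out fits 4750 of 6316 were kept and 0 turned around. Genes named for replicates that do not overlap could not turn around when a library was left out, so for them this was fixed beforehand. Not run, because the values are not counts, were DESeq2 size factors, a DESeq2 test, a filter on raw counts and DESeq2 calls in the overlaps, and all 6 colon groups in 1 fit was not run for want of a common scale. Of simulated 2-fold changes 11.5% (high GFP), 22.7% (low GFP) and 12.5% (high against low) were recovered in the sorts of the small intestine, against 52.1% and 77.9% in those of the normal and DSS colon, and depth was not separated from spread.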

Other observations

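Some genes best known from hepatocytes were higher in the GFP sorts of the small intestine than in unsorted cells. Asgr1 was read at 2043 ± 1020.3 (SD, n = 3) in low-GFP cells against 8.5 ± 12.02 (SD, n = 2) in unsorted cells, Cyp2c29 at 2132 ± 1389 (SD, n = 3) against 4 ± 5.66 (SD, n = 2), and Cyp3a11 at 1293 ± 1483 (SD, n = 3) in high-GFP cells against 6.5 ± 9.19 (SD, n = 2). Against GFP-negative cells these genes did not pass, with 2.98 for Asgr1 (limma adjusted p = 0.48) and 3.91 for Cyp2c29 (0.54) in low-GFP cells and 3.27 for Cyp3a11 (0.78) in high-GFP cells, so they are not shown to belong to the GFP sorts. They were named by the rule on the largest changes, no list of such genes was tested, and their origin was not tested.

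All tests weighed here were chosen after the result was seen, except the one on Syn3 and Timp3.

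Fabp6 and Reg3b were lower in low-GFP than in GFP-negative cells of the small intestine. The deepest GFP-negative library held at least 82.4 times the highest low-GFP value of either gene, but this decides nothing about depth, since lower depth would not raise the genes in the GFP-negative libraries. Epithelial cells carried into the GFP-negative sort may account for it: over the 28 other epithelial genes the GFP-negative libraries stood at medians of 2.59%, 17.0% and 0.362% of the unsorted level. Fabp6 stood at 28.4%, 53.4% and 12.7% in the same libraries and Reg3b at 63.3%, 177% and 10%, above these medians but in the same order of libraries, so that carry-over of epithelium and expression in mesenchymal cells cannot be told apart.

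After DSS 21 of 34 cytokine and chemokine and 19 of 31 interferon-stimulated genes rose in GFP-positive colon cells (adjusted p = 0.17 with an estimated correlation and 0.21 for the lists), and 23 of 33 and 21 of 32 in GFP-negative cells (0.21 and 0.20). Carry-over of immune cells as a whole is an unlikely cause of most of it. The immune markers reached at most a median of 2.96% of the unsorted DSS level in any sorted library. The risen members stood at medians of 82.6% (GFP-positive) and 120.7% (GFP-negative), but they were picked by their rise in these same libraries, which favours high percentages. A median over many markers also cannot exclude 1 carried-over cell type, and the neutrophil gene S100a8 rose in GFP-negative cells. Other carried-over cells were not weighed. DSS and library series cannot be told apart in the colon, since 0 library series hold both normal and DSS sorted colon libraries, a series being inferred from the library numbers alone, as the labels name no batch, and this value being fixed by the design. The normal small intestine, numbered next to the DSS colon, is another tissue on another scale and was not used to separate them. That the mesenchymal cells themselves express these genes in colitis is a hypothesis for which cells of both treatments in 1 series are needed.

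Timp3 and Syn3, which overlap on opposite strands, rose together in GFP-positive cells after DSS. The ratio of Syn3 to Timp3 ranged 2.45 times over the 12 sorted colon libraries, while Timp3 itself ranged 7.25 times and Syn3 12.7 times. Reads of Timp3 counted for Syn3 might explain this narrow ratio, but joint regulation and shared reads cannot be told apart.

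Relabelling the libraries in all 10 possible splits gave the real grouping the most genes in each comparison with 3 libraries a side, with 1 split (the real one) at its count. The 10 splits are too few for a share under 0.05. The other splits also put real group differences into the spread, which lowers their counts, so low counts there decide nothing. The highest other count was 11 against 84 for low GFP, 40 against 47 for high against low GFP and 0 in the other comparisons: 798 and 2152 (normal and DSS colon), 2555 and 1341 (DSS responses), 111 (high GFP), and 3197, 2753, 5070 and 4509 (colon against unsorted).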
